A study of Mus musculus with 6 samples.

How the data were processed

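Mouse liver RNA of 2 diet groups was measured on Affymetrix Mouse Genome 430 2.0 arrays, 3 per group. Per the labels' protocols RNA was isolated with TRIzol, 10 µg was labelled with biotin in a one-cycle reaction, and RNA of 2 mice was pooled. The deposited values are log2 expression levels per probe set, made by the authors with RMA (background correction, quantile normalization and summary of probes) in Affymetrix Expression Console 1.0, per the submitters' processing notes. Scanner files were not used here. The table held 45101 probe sets and 0 missing values. RMA compresses differences near background, so folds of genes with low levels in 1 group understate the change.

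After 64 control probe sets were left out, 45037 remained. Of these 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 are unnamed here. The gene ID of 34741 probe sets was found in a gene table of the assembly GRCm38.p6, used for names only, and 0 symbols changed. Each of 18193 genes was represented by its probe set with the highest mean and kept if above the 40th percentile of an array's probe sets in at least 3 of 6 arrays. Probe sets of a gene sometimes differed, as for Acaca, Acsl3, B3galt1, Bdh1, Col5a2, Dcn, Ddx58, Egfr, Fdft1, Fdps, Hspa8, Il1r1, Klf6, Mcm6, Ntrk2, Osbpl3, Rad51b, Scara5, Scd1, Scd2, Socs2, Thrsp, Top2a and Trib3, and many named genes rest on probe sets designed to match several transcripts.

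Groups came from the sample labels. limma 3.58.1 in R 4.3.3 fitted high-fat against normal diet with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and calls at an adjusted p below 0.05. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests a list on its own, adjusted over 32 lists with at least 5 tested members. Of 809 list entries 728 matched a gene, 7 of them by an older symbol. Tables were summarised with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

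The lists, the tests of genes and lists and the naming rule were fixed before the data were examined, and some tests of technical explanations were not. Named genes were the 15 largest increases and 15 largest decreases among called genes whose groups do not overlap, up to 4 members of each list with the smallest p, of which some are not named, and 35 landmark genes whatever their result. Of these 32 were tested, and the others are not reported here. Alternatives were other level filters and a floor, other variance models, a plain equal-variance test per gene, further scaling of the arrays, other choices of probe set, stricter thresholds, a replicate block and each array left out in turn. On simulated data of 14071 genes the test recovered 22.4% of genes changed 1.5-fold, 77.6% changed 2-fold and 98.5% changed 4-fold. Of its calls 5.04% were false, and limma made 0 calls where no gene was changed. The simulated genes were independent, with variances drawn from limma's fit and equal spread in both diets. The measured arrays had unequal spread and correlated genes, so these rates need not hold for them.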

Results

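Liver gene expression was measured in male C57BL/6 mice, an inbred laboratory strain, after 12 weeks on either a normal diet or a high-fat diet with 60% of its calories from fat. Feeding began at 8 weeks of age, and each diet had 6 mice. RNA was combined in pairs of mice, read here as 3 pools of 2 mice per diet, and each pool was hybridised to its own Affymetrix Mouse Genome 430 2.0 array. The array is therefore the replicate (n = 3 per diet). The p-values weigh a difference against the spread between arrays of pools, not between single mice. Values are log2 expression levels, and differences are given as high-fat minus normal diet ± the standard error (SE) of limma's fit. After a filter on low levels 14071 genes were tested, and the number of arrays limits the precision.

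The 3 high-fat arrays resembled each other more closely than the 3 normal diet arrays did. Across probe sets, which are not independent replicates, Pearson's r between arrays was 0.994 to 0.995 within the high-fat group, 0.984 to 0.992 within the normal diet group and 0.974 to 0.988 between groups. The median SD of a gene was 0.117 in the high-fat group and 0.166 in the normal diet group. Normal diet 3 stood apart on the component that separated the diets, with a score of -46.2 against -15.6 and -12.5 for normal diet 1 and 2 and 24.3 to 25.4 for the high-fat arrays. The 3' to 5' log2 difference of the Gapdh control probe sets, a measure of RNA integrity, was 0.36 in normal diet 1 and between -0.19 and 0.01 in the other arrays.

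**Figure D1:**
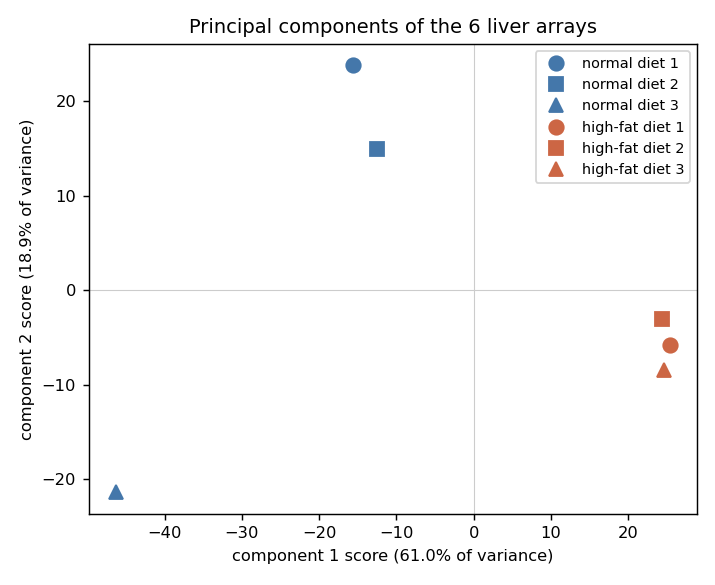
Scores of the 6 arrays on the leading principal components of the 14071 tested genes, with the share of variance on each axis (61.0% and 18.9%). Colour marks the diet and the marker shape the replicate number, and normal diet 3 lies at -46.2 on component 1, far from the high-fat arrays at 24.3 to 25.4.

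The comparison of high-fat with normal diet asked which liver genes differed, in a design aimed at the handling of lipids in obesity. Cidea, which encodes a lipid droplet protein, was 77.1-fold higher under the high-fat diet (log2 6.27 ± 1.31, n = 3 arrays per diet, limma adjusted p = 0.0328). Sult1e1, the oestrogen sulfotransferase gene, rose 11.0-fold (3.46 ± 0.39), Gstm3, a glutathione S-transferase gene, 9.68-fold (3.28 ± 0.44), and Cidec, a further lipid droplet gene, 6.86-fold (2.78 ± 0.60). Cyp7b1, the oxysterol hydroxylase gene of the alternative bile acid pathway, was 21.5-fold lower (-4.43 ± 0.58, limma adjusted p = 0.00860). Slco1a1, an organic anion transporter gene, was 15.4-fold lower (-3.94 ± 0.43), Socs2, a feedback inhibitor of growth hormone signalling, 15.2-fold lower (-3.92 ± 0.24), and Saa2, a serum amyloid A gene, 12.9-fold lower (-3.69 ± 0.15). The Cidec difference was 2.01 without normal diet 1, and Cidec was not called with a replicate block (adjusted p = 0.0549) or without high-fat 1, 2 or 3 (adjusted p = 0.131, 0.119 and 0.119). The Cidea and Cyp7b1 differences were 8.04 and -5.18 without normal diet 2. Gstm3 was not called without high-fat 3 (adjusted p = 0.0523). Cyp7b1 and Socs2 differed by -3.05 and -1.52 with the mean of the probe sets. Cidea differed by 5.36 without normal diet 1, 5.40 without normal diet 3 and 5.17 with array weights.

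In all, 1070 of 14071 genes differed at an adjusted p below 0.05 (limma), 826 of them higher and 244 lower under the high-fat diet. At 2-fold or more 234 were higher and 97 lower, and at 4-fold or more 29 and 27. The arrays of the diets did not overlap in any of the 1070 genes, which held for 35.8% of all tested genes against 10% by chance. Of the calls, 77.2% were higher. This share depended on scaling: it was 66.4% after quantile normalization (596 higher and 301 lower genes), 69.8% after cyclic loess and 82.9% after median centring. Leaving out high-fat 1, 2 or 3 gave 272, 217 and 169 genes, and leaving out normal diet 1, 2 or 3 gave 1065, 949 and 1245. Of the 111 genes named here that were called with all arrays, 54, 46 and 44 kept their call without high-fat 1, 2 and 3, and 89, 95 and 107 without normal diet 1, 2 and 3.

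Further genes among the 15 largest increases were Rad51b, a recombination gene (14.9-fold, 3.90 ± 0.24), Sprr1a (9.01-fold), Osbpl3, an oxysterol-binding protein gene (8.04-fold), Ly6d (7.39-fold), Sdcbp2 (6.01-fold), Tceal8 (5.87-fold), the water channel gene Aqp8 (5.71-fold), the carbonyl reductase gene Cbr3 (5.30-fold) and Clec7a, which encodes the receptor dectin-1 (5.30-fold). Another probe set of Rad51b, at 2.96 and 2.94, differed by -0.02. Among the 15 largest decreases were also Scara5, a ferritin receptor gene (11.0-fold lower), B3galt1, a galactosyltransferase gene (10.6-fold lower), the chemokine gene Cxcl1 (10.4-fold lower), Tifa (7.83-fold lower), the interleukin 1 receptor gene Il1r1 (6.65-fold lower), the pseudogene Serpina4-ps1 (19.2-fold lower) and Mup10, a major urinary protein gene (6.68-fold lower). Probe sets of the Saa, Mup and Gstm families can pick up near-identical copies, so their assignment to 1 member is uncertain. Cidea lay at 3.38 and 3.45 in normal diet 1 and 3, below the level filter of those arrays (3.54 and 3.59), at 8.73 in normal diet 2 and at a mean of 11.45 in the high-fat arrays. Without normal diet 2 the Cidea difference was 8.04 (adjusted p = 9.04e-06), and without normal diet 3 it was 5.40 (adjusted p = 0.0384). Cidea was not called without normal diet 1 (5.36, adjusted p = 0.0624) or without high-fat 1, 2 or 3 (adjusted p = 0.117, 0.117 and 0.118). Without normal diet 3, Ly6d differed by 3.67, Sprr1a by 3.79 and Tifa by -2.25, and without normal diet 2 Tceal8 differed by 3.24, against 2.89, 3.17, -2.97 and 2.55 with all arrays. Calls ended for Ly6d and Tceal8 without normal diet 1 (2.39 and 2.17, adjusted p = 0.0555 and 0.0546) and for Ly6d without normal diet 2 (2.59, adjusted p = 0.0732). Sprr1a, Ly6d, Tceal8, Aqp8 and Tifa were not called whichever high-fat array was left out (adjusted p from 0.0523 to 0.127). Cxcl1 was not called without high-fat 2 or 3 (adjusted p from 0.0508 to 0.0542). Rad51b, Osbpl3, Scara5, B3galt1 and Il1r1 differed by 1.94, 1.79, -2.005, -1.93 and -1.35 with the mean of the probe sets.

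**Figure D2:**
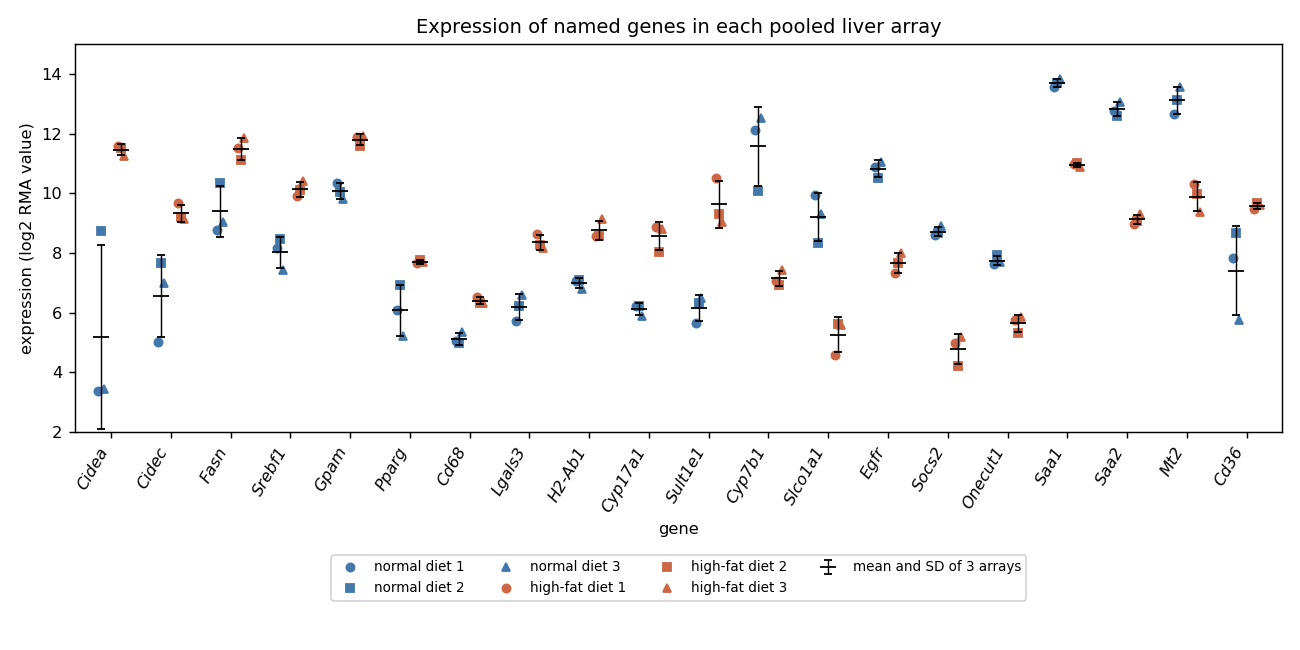
Log2 RMA expression of 20 named genes in each array, with normal diet in blue and high-fat diet in red, marker shapes for the replicate number, and bars for the mean and SD of 3 arrays. Cidea lies at 8.73 in normal diet 2 and at 3.38 and 3.45 in normal diet 1 and 3, and Cd36 did not pass the test (adjusted p = 0.0832).

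Genes were also grouped in 32 lists fixed before the data were examined. Camera called 19 lists with its preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.364, 2 lists at an unadjusted p below 0.05), while fry called 14. Fry, which tests a list on its own, did not call 7 of the camera calls: heat shock (adjusted p = 0.0851), PPARalpha targets (0.222), endoplasmic reticulum stress (0.171), endothelial (0.0618), female-biased (0.0618), glucose (0.222) and interferon genes (0.0529). It called a pair of lists that camera did not, NRF2 (0.0148) and lipoprotein genes (0.0168). Each of the 9 other splits of the 6 arrays into 3 and 3 also had lists called by camera, up to 17. Limma called 0 genes in each, with 194 to 434 genes at an unadjusted p below 0.05. These splits mix the diets in both groups, so they are not comparisons free of a diet difference.

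Of 23 tested genes of fatty acid synthesis 10 rose, 0 fell and 13 were not called, and 19 rose when adjusted over the list alone. Fasn, which encodes fatty acid synthase, rose 4.27-fold (2.10 ± 0.40), Srebf1, whose product drives lipogenic genes, 4.31-fold (2.11 ± 0.26), the desaturase gene Scd2 4.77-fold (2.25 ± 0.22) and Acaca, which encodes acetyl-CoA carboxylase, 2.61-fold (1.39 ± 0.23). Pgd and Tkt, of the pentose phosphate pathway, rose 3.34-fold and 2.07-fold. Camera gave an adjusted p of 1.33e-09, and the adjusted p was 0.364 with an estimated correlation. Without normal diet 1, 2 and 3, 7, 17 and 9 members were called higher, and 3 whichever high-fat array was left out. Scd1 and Thrsp were 1.68-fold and 3.48-fold higher without passing (adjusted p = 0.0537 and 0.187), and the Thrsp difference was 0.79 without normal diet 3 and 2.57 without normal diet 2. Scd1 passed without normal diet 2 (0.97), after median centring (0.80), with trend and robust variance (0.75, adjusted p = 0.0448) and with the mean of its probe sets (1.42, adjusted p = 0.0455). The Scd1 probe set used lay at 13.40 and 14.15, and the other one differed by 2.10 (adjusted p = 0.0498 with probe sets tested one by one). Mlxipl, which encodes the carbohydrate response factor ChREBP, differed by -0.02 ± 0.21 and was not called. Fasn, Acaca and Tkt were not called whichever high-fat array was left out (adjusted p from 0.0560 to 0.109). Scd2 and Acaca differed by 0.82 and 0.80 with the mean of the probe sets. Mlxipl differed by 0.022 without normal diet 1, 0.093 without normal diet 2, -0.18 without normal diet 3, 0.17 without high-fat 1 and -0.19 without high-fat 3. Thrsp differed by 1.08 with array weights.

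Among 26 genes of triglyceride synthesis and lipid droplets 5 rose, 0 fell and 21 were not called (10 higher adjusted over the list alone). They were Cidea and Cidec, the acyltransferase genes Gpam (3.28-fold, 1.71 ± 0.16) and Agpat2 (1.49-fold), and Plin3, a droplet coat gene (1.77-fold). Mogat1 and Plin4 lay 4.56-fold and 2.50-fold higher without passing (adjusted p = 0.0510 and 0.0641), and both passed without normal diet 2 (2.90 and 1.75). Plin2, another coat gene, differed by 0.18 ± 0.24 and was not called. The camera adjusted p was 2.37e-05, against an adjusted p of 0.364 with an estimated correlation. The 5 became 2 whichever high-fat array was left out and 4, 8 and 6 without normal diet 1, 2 and 3. The call ended for Agpat2 with a replicate block (0.58, adjusted p = 0.0612). Agpat2 was not called whichever high-fat array was left out (adjusted p from 0.0742 to 0.113). Mogat1 also passed after median centring (2.24) and Plin4 with a replicate block (adjusted p = 0.0370). Plin2 differed by -0.093 without normal diet 1, 0.44 without normal diet 3 and 0.055 after cyclic loess.

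Of 16 genes of fatty acid uptake and binding 4 rose, 0 fell and 12 were not called (6 higher adjusted over the list alone). Acsl3, an acyl-CoA synthetase gene, rose 2.64-fold, Fabp2, a fatty acid-binding protein gene, 2.35-fold, Pparg, a lipogenic nuclear receptor gene, 3.09-fold (1.63 ± 0.37), and the transporter gene Slc27a4 1.52-fold. Cd36, the fatty acid translocase gene, was 4.51-fold higher (2.17 ± 0.64) without passing (adjusted p = 0.0832), but passed without normal diet 2 (2.80, adjusted p = 0.0352) and without normal diet 3 (1.34, adjusted p = 0.0120). Camera gave an adjusted p of 0.0181 (adjusted p = 0.364 with an estimated correlation), which became 0.0510 after cyclic loess. The list was also not called with probe sets without a suffix. The 4 became 1, 1 and 0 without high-fat 1, 2 and 3 and 2, 5 and 6 without normal diet 1, 2 and 3. Slc27a4 lost its call after cyclic loess (0.51) and quantile normalization (0.48), and Pparg after the latter (1.53) and without normal diet 1 (1.63). Calls ended for Slc27a4 without normal diet 1 (0.58, adjusted p = 0.0794), for Slc27a4 without normal diet 3 (0.51, adjusted p = 0.0571) and for Slc27a4 with a replicate block (0.61, adjusted p = 0.0650). Acsl3 was not called without high-fat 3 (adjusted p = 0.0507). Fabp2, Pparg and Slc27a4 were not called whichever high-fat array was left out (adjusted p from 0.0543 to 0.146). Acsl3 differed by 0.84 with the mean of the probe sets.

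Of 20 genes of cholesterol synthesis and uptake 3 rose, 0 fell and 17 were not called (4 higher adjusted over the list alone). Hmgcs1, of the mevalonate pathway, rose 2.46-fold (1.30 ± 0.16), Fdft1, which encodes squalene synthase, 2.28-fold, and Fdps 1.86-fold, while Sqle, which encodes squalene epoxidase, was not called (-0.50 ± 0.31). Insig1, a regulator of sterol synthesis, was 2.45-fold higher without passing (adjusted p = 0.0548), and passed without normal diet 1 (1.63), without normal diet 3 (0.92) and with array weights (1.13). Insig2, a regulator of sterol synthesis outside the list, differed by 0.57 ± 0.25 and was not called. With probe sets tested one by one, other Insig2 probe sets differed by 0.93 (adjusted p = 0.0150) and 0.81 (adjusted p = 0.0522). Camera gave an adjusted p of 0.0282, and 0.364 was the adjusted p with an estimated correlation. The list was not called after quantile normalization (adjusted p = 0.0912), after cyclic loess (0.182), without high-fat 1 (0.0731) or with probe sets without a suffix. Of its genes, 1 was higher whichever high-fat array was left out. Fdps lost its call after cyclic loess (0.76), without normal diet 1 (0.74) and without normal diet 3 (0.82). A pair of weaker Fdft1 probe sets did not move with the one used. Calls ended for Fdft1 without normal diet 2 (1.15, adjusted p = 0.0501), for Fdft1 and Fdps with the mean of the probe sets (0.44 and 0.41, adjusted p = 0.0662 and 0.0712) and for Fdps with a replicate block (0.90, adjusted p = 0.0528). Fdft1 and Fdps were not called whichever high-fat array was left out (adjusted p from 0.0624 to 0.135). Insig2 differed by 0.28 without normal diet 1. Sqle differed by -0.79 without normal diet 2, -0.17 without normal diet 3 and -0.24 with array weights.

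Of 24 genes of glucose metabolism and insulin signalling 5 rose, 3 fell and 16 were not called (10 higher and 3 lower adjusted over the list alone). G6pc, which encodes the catalytic subunit of glucose-6-phosphatase, rose 5.10-fold (2.35 ± 0.48), and Ppp1r3g, a glycogen-targeting subunit gene, 2.12-fold. Irs2, an insulin receptor substrate gene, was 1.91-fold lower, Igf1 1.58-fold lower (-0.66 ± 0.14) and Igfbp2 4.67-fold lower. Pck1 and Igfbp1 did not pass, at 0.33 ± 0.23 and 0.75 ± 0.58. Without normal diet 3 Igfbp1 differed by 0.033 and G6pc by 1.76, and without normal diet 2 Igfbp2 by -2.86. The camera adjusted p was 0.0404 (adjusted p = 0.588 with an estimated correlation). It became 0.115 after cyclic loess, 0.0812 after median centring, 0.202 without normal diet 3 and 0.0812 without high-fat 1. Camera also did not call the list with the level filter at the median or with array weights. Whichever high-fat array was left out, limma called 0 members, and without normal diet 1, 2 and 3 it called 2, 6 and 3 higher and 2, 2 and 2 lower. Calls ended for Igfbp2 without normal diet 1 (-1.76, adjusted p = 0.0671), for Ppp1r3g and Igf1 without normal diet 2 (1.18 and -0.61, adjusted p = 0.0583 and 0.0804) and for Igfbp2 without normal diet 3 (-2.05, adjusted p = 0.0585). Calls ended for Igfbp2 with array weights (-1.81, adjusted p = 0.0518), for Igfbp2 with the mean of the probe sets (-2.22, adjusted p = 0.0507) and for Igf1 with probe sets without a suffix (-0.58, adjusted p = 0.133). Calls ended for G6pc, Ppp1r3g and Igfbp2 with a replicate block (2.35, 1.08 and -2.22, adjusted p = 0.0550, 0.0696 and 0.0658). G6pc, Ppp1r3g, Irs2, Igf1 and Igfbp2 were not called whichever high-fat array was left out (adjusted p from 0.0518 to 0.155). Pck1 differed by 0.55 without normal diet 1, 0.10 without normal diet 3 and 0.20 after cyclic loess. Igfbp1 differed by 1.32 without normal diet 2 and 0.19 with array weights.

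Of 34 PPARalpha targets and fatty acid oxidation genes 2 rose, 0 fell and 32 were not called, with 2 higher adjusted over the list alone. These were Fgf21, which encodes a hormone released by the liver (2.70-fold, 1.43 ± 0.18), and Bdh1, a ketone body enzyme gene (1.58-fold). Cpt1a, the gate of mitochondrial fatty acid import, differed by 0.39 ± 0.25, Cyp4a14 by 1.81 ± 1.40 and Pdk4, a pyruvate dehydrogenase kinase gene, by 1.61 ± 0.61, without passing. Aldh3a2, a fatty aldehyde dehydrogenase gene, was 2.51-fold higher without passing (adjusted p = 0.0713), and passed without normal diet 2 (1.64), without normal diet 3 (0.86) and with array weights (1.04). Without normal diet 3 the Cyp4a14 and Pdk4 differences were -0.077 and 0.85, and Cyp4a14 differed by 2.81 and 2.71 without normal diet 1 and 2. By camera the adjusted p was 1.16e-04 for a shift upward (adjusted p = 0.588 with an estimated correlation). With normal diet 2 left out, 5 members were called higher, and 1 whichever high-fat array was left out. Bdh1 was not called whichever high-fat array was left out (adjusted p from 0.0594 to 0.0718). Bdh1 differed by 0.36 with the mean of the probe sets. Cpt1a differed by 0.13 without normal diet 3, 0.26 after cyclic loess, 0.25 with array weights and 0.21 without high-fat 1. Cyp4a14 differed by 0.70 with array weights.

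In the bile acid list 2 of 23 genes rose, 2 fell and 19 were not called (2 and 2 adjusted over the list alone). Nr0b2, a repressor of bile acid synthesis genes, rose 2.21-fold and Hsd3b7 1.5-fold, while Cyp7b1 and Slco1a1 fell. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -0.01 ± 0.84 and Cyp8b1 by 0.79 ± 0.27, neither called, and without normal diet 1 and 3 Cyp7a1 differed by 0.82 and -1.08. The median member was at 0.25 and the mean at -0.11, camera's direction was upward, and the list was not called (adjusted p = 0.668). Hsd3b7 lost its call after cyclic loess (0.45) and quantile normalization (0.52), and Cyp8b1 passed without normal diet 1 (1.11, adjusted p = 0.0153). Higher members numbered 1, 0 and 0 without high-fat 1, 2 and 3. Calls ended for Hsd3b7 without normal diet 1 (0.53, adjusted p = 0.0775) and for Hsd3b7 without normal diet 2 (0.56, adjusted p = 0.0836). Nr0b2 was not called without high-fat 2 or 3 (adjusted p from 0.0518 to 0.0645). Hsd3b7 was not called whichever high-fat array was left out (adjusted p from 0.0710 to 0.129). Cyp7a1 differed by 0.22 without normal diet 2, -0.53 with array weights and 0.16 without high-fat 2.

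Lipoprotein genes moved in both directions, with 3 of 19 higher, 1 lower and 15 not called (4 and 2 adjusted over the list alone; camera adjusted p = 0.522, fry adjusted p = 0.0168). Apoa4, an apolipoprotein gene, rose 4.07-fold (2.03 ± 0.36), Angptl8, whose product inhibits lipoprotein lipase, 2.35-fold, and Apoc2 2.17-fold, while Apom was 1.84-fold lower. Without high-fat 1, 2 and 3, 1, 1 and 0 lipoprotein genes were called higher and 0 lower. Among 38 genes of xenobiotic metabolism 5 rose, 6 fell and 27 were not called (6 and 7 adjusted over the list alone; camera adjusted p = 0.434). Besides Gstm3, Gstm1 rose 1.86-fold, whereas Cyp2c70 was 3.54-fold lower (-1.82 ± 0.23) and the carboxylesterase gene Ces2a 2.00-fold lower. Without normal diet 2, 9 of these were higher, and 1, 1 and 0 were higher without high-fat 1, 2 and 3, with 1 lower each time. Calls ended for Apom without normal diet 1 (-0.80, adjusted p = 0.0810) and for Apom with a replicate block (-0.88, adjusted p = 0.0638). Apoa4, Apoc2, Apom, Gstm1 and Ces2a were not called whichever high-fat array was left out (adjusted p from 0.0514 to 0.146). Angptl8 was not called without high-fat 3 (adjusted p = 0.0665).

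Of 18 male-biased genes, which are higher in male than in female mouse liver, 10 fell, 0 rose and 8 were not called (12 lower adjusted over the list alone). Egfr, the epidermal growth factor receptor gene, was 8.89-fold lower (-3.15 ± 0.20) and Nudt7 2.48-fold lower, beside Cyp7b1 and Slco1a1. Of 14 female-biased genes 4 rose, 0 fell and 10 were not called (5 higher adjusted over the list alone). Cyp17a1, a steroid hydroxylase gene, rose 5.42-fold (2.44 ± 0.23), Ntrk2, a neurotrophin receptor gene, 2.40-fold, and Slc22a27 3.12-fold, beside Sult1e1. Camera gave adjusted p values of 9.03e-10 and 0.00509, and the adjusted p values were 0.364 and 0.431 with an estimated correlation. The female-biased list was not called without normal diet 3 (adjusted p = 0.0990) or with array weights. Without normal diet 1, 2 and 3, 6, 12 and 9 male-biased genes were lower and 3, 6 and 4 female-biased genes higher, while the counts were 5, 5 and 4 and 3, 3 and 3 without high-fat 1, 2 and 3. Calls ended for Slc22a27 without normal diet 1 (1.64, adjusted p = 0.0530) and for Slc22a27 with a replicate block (1.64, adjusted p = 0.0638). Slc22a27 was not called whichever high-fat array was left out (adjusted p from 0.0514 to 0.0940). Egfr and Ntrk2 differed by -1.56 and 0.40 with the mean of the probe sets.

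Of 27 acute phase genes 12 fell, 0 rose and 15 were not called (16 lower adjusted over the list alone). Saa1, a serum amyloid A gene, was 6.70-fold lower (-2.74 ± 0.11, adjusted p = 1.46e-04), the metallothionein genes Mt1 and Mt2 were 5.79-fold and 9.38-fold lower (-2.53 ± 0.24 and -3.23 ± 0.29), Steap4 was 4.36-fold lower, and Socs3, a feedback inhibitor of cytokine signalling, 5.96-fold lower. Lcn2 lay 4.45-fold lower (-2.15 ± 0.59) without passing (adjusted p = 0.0712), and passed without normal diet 1 (-2.87) and with array weights (-2.09). The camera test of the list gave an adjusted p of 2.26e-13, and the adjusted p was 0.364 with an estimated correlation. The 12 became 6, 7 and 5 without high-fat 1, 2 and 3 and 13, 12 and 13 without normal diet 1, 2 and 3. In the normal diet arrays Saa1, Saa2, Mt1 and Mt2 ranked at percentile 99.7 of the probe sets or higher. The call ended for Mt1 with probe sets without a suffix (-1.75, adjusted p = 0.0542). Socs3 was not called whichever high-fat array was left out (adjusted p from 0.0825 to 0.0895).

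Xbp1, a transcription factor gene of the unfolded protein response, was 2.79-fold lower (-1.48 ± 0.13), the endoplasmic reticulum chaperone genes Hsp90b1 and Dnajc3 were 1.67-fold and 1.54-fold lower, and Trib3 rose 1.61-fold. Of 29 genes of endoplasmic reticulum and integrated stress 1 rose, 3 fell and 25 were not called (3 and 7 adjusted over the list alone). Of 12 heat shock genes Hsp90aa1 and Hspa8 fell by 0.91 ± 0.17 and 0.59 ± 0.14 on the log2 scale, 0 rose and 10 were not called (6 lower adjusted over the list alone). Camera adjusted p values were 0.00166 and 5.88e-05 (adjusted p = 0.431 and 0.412 with an estimated correlation). Hsph1, of the heat shock list, was 2.19-fold lower without passing (adjusted p = 0.0551), and passed without normal diet 3 (-1.41), after quantile normalization (-1.26), after cyclic loess (-1.26), with array weights (-1.31) and with a replicate block (adjusted p = 0.0419). Hspa8 lost its call after median centring (-0.54) and quantile normalization (-0.57) and with probe sets without a suffix (-0.12, adjusted p = 0.548, at a low level), with a replicate block, without normal diet 1 (-0.47) or 2 (-0.60, adjusted p = 0.0881) and whichever high-fat array was left out (adjusted p = 0.161, 0.114 and 0.155), and Hsp90b1 after median centring (-0.69). Without normal diet 1, 2 and 3, 2, 0 and 5 heat shock genes and 2, 1 and 4 of the stress list were lower, against 0 and 1 whichever high-fat array was left out. Calls ended for Hsp90b1 without normal diet 1 (-0.76, adjusted p = 0.0704), for Hsp90b1, Dnajc3 and Hsp90aa1 without normal diet 2 (-0.65, -0.54 and -0.88, adjusted p = 0.0966, 0.0732 and 0.0532) and for Hsp90b1 and Dnajc3 with the mean of the probe sets (-0.68 and -0.48, adjusted p = 0.0839 and 0.107). The call ended for Hsp90aa1 with probe sets without a suffix (-0.80, adjusted p = 0.102). Hsp90b1, Dnajc3 and Hsp90aa1 were not called whichever high-fat array was left out (adjusted p from 0.0514 to 0.121). Trib3 was not called without high-fat 1 or 2 (adjusted p from 0.0740 to 0.0900). Trib3 differed by 0.42 with the mean of the probe sets.

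Of 19 hepatocyte identity genes 5 fell, 0 rose and 14 were not called (6 lower adjusted over the list alone). Onecut1 was 4.30-fold lower (-2.10 ± 0.16), Foxa3 2.53-fold, Foxa1 2.41-fold and Hnf4a 1.62-fold lower, all genes of transcription factors. Hnf4a was not called with the mean of its probe sets (-0.48, adjusted p = 0.0635) or with probe sets without a suffix (-0.41, adjusted p = 0.215), or without high-fat 1, 2 or 3 (adjusted p = 0.0555, 0.0508 and 0.0619). Over 8 abundant transcripts of secreted hepatocyte proteins the mean difference was -0.02 (SE 0.0550 over genes). For the list camera's adjusted p was 0.00337, and the adjusted p was 0.364 with an estimated correlation. The 5 became 2 whichever high-fat array was left out and 4, 3 and 5 without normal diet 1, 2 and 3. The call ended for Foxa1 without normal diet 2 (-1.23, adjusted p = 0.0585). Foxa1 was not called whichever high-fat array was left out (adjusted p from 0.0744 to 0.109).

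Of 31 macrophage and Kupffer cell markers 18 rose, 0 fell and 13 were not called (21 higher and 2 lower adjusted over the list alone). Lgals3, which encodes galectin-3, rose 4.55-fold (2.19 ± 0.23), the lysosomal marker Cd68 2.42-fold (1.28 ± 0.13), the protease gene Ctss 1.93-fold, Mpeg1 1.81-fold and Adgre1, which encodes F4/80, 1.56-fold. With camera the list had an adjusted p of 1.21e-07, and the adjusted p was 0.364 with an estimated correlation. The 18 became 8, 4 and 4 without high-fat 1, 2 and 3 and 16, 14 and 20 without normal diet 1, 2 and 3, and Adgre1 lost its call after cyclic loess (0.52) and quantile normalization (0.49). Of 17 lymphocyte and NK cell markers 4 rose, 0 fell and 13 were not called (5 higher adjusted over the list alone; camera adjusted p = 0.522). They were the MHC class II genes H2-Ab1 (3.42-fold, 1.78 ± 0.18) and H2-Aa (2.55-fold), Cd74, the invariant chain gene (2.31-fold), and the chemokine gene Ccl5 (1.81-fold). Macrophages also express the class II genes and Cd74. Without high-fat 1, 2 and 3, 3, 1 and 2 genes of the lymphocyte list were higher. Calls ended for Adgre1 without normal diet 1 (0.63, adjusted p = 0.0805), for Adgre1 and Ccl5 without normal diet 2 (0.54 and 0.82, adjusted p = 0.0977 and 0.0879) and for Ccl5 without normal diet 3 (0.75, adjusted p = 0.0561). Calls ended for Adgre1 with trend and robust variance (0.64, adjusted p = 0.0505) and for Ccl5 with a replicate block (0.85, adjusted p = 0.0870). Mpeg1 and Ccl5 were not called without high-fat 2 or 3 (adjusted p from 0.0518 to 0.146). Adgre1 and Cd74 were not called whichever high-fat array was left out (adjusted p from 0.0533 to 0.143). H2-Aa was not called without high-fat 2 (adjusted p = 0.0523).

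Of 27 stellate cell and fibrosis genes 5 rose, 0 fell and 22 were not called (11 higher adjusted over the list alone). The collagen genes Col3a1, Col1a2 and Col5a2 rose 4.92-fold (2.30 ± 0.47), 2.52-fold and 2.34-fold, and Dcn, which encodes decorin, 1.55-fold, while Col1a1 differed by 0.21 ± 0.15 and was not called. The list had a camera adjusted p of 6.36e-05 (adjusted p = 0.364 with an estimated correlation). The 5 became 4, 0 and 0 without high-fat 1, 2 and 3 and 1, 4 and 6 without normal diet 1, 2 and 3, and Col1a2 lost its call after quantile normalization (1.21). Of 23 sinusoidal endothelial markers Lyve1 and Emcn rose, 2.56-fold and 1.64-fold, 0 fell and 21 were not called (3 higher adjusted over the list alone). The camera adjusted p was 0.00169, against an adjusted p of 0.431 with an estimated correlation, and limma called 0 members whichever high-fat array was left out. Calls ended for Col3a1, Col1a2 and Col5a2 without normal diet 1 (2.10, 1.19 and 1.21, adjusted p = 0.0652, 0.0765 and 0.0651), for Col3a1, Col1a2 and Col5a2 without normal diet 2 (2.36, 1.35 and 1.25, adjusted p = 0.0624, 0.0753 and 0.0670) and for Col3a1, Col1a2, Col5a2 and Dcn with the mean of the probe sets (1.55, 0.94, 0.68 and 0.26, adjusted p = 0.0566, 0.0851, 0.0511 and 0.101). The call ended for Col1a2 with probe sets without a suffix (1.49, adjusted p = 0.121). Col3a1, Col1a2 and Col5a2 were not called without high-fat 2 or 3 (adjusted p from 0.0730 to 0.126). Dcn, Lyve1 and Emcn were not called whichever high-fat array was left out (adjusted p from 0.0523 to 0.0883). Col1a1 differed by 0.11 without normal diet 2, 0.32 without high-fat 1, 0.081 without high-fat 2 and 0.38 with the mean of the probe sets. The Col1a1 probe set used lay at low levels, 4.29 under normal and 4.49 under high-fat diet. Another Col1a1 probe set differed by 0.56 (limma adjusted p = 0.0905 with probe sets tested one by one).

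Of 22 cell cycle genes 6 rose, 0 fell and 16 were not called (12 higher adjusted over the list alone). Mcm6, a replication helicase gene, rose 2.26-fold (1.17 ± 0.18), Ccnb2 2.01-fold, Birc5 1.73-fold and Top2a 1.56-fold. Their levels were low, with normal diet means of 3.39 for Ccnb2 and 3.06 for Birc5, and other Top2a probe sets differed by -0.23 and 0.01. By camera the adjusted p was 6.36e-05, and the adjusted p was 0.364 with an estimated correlation. Without high-fat 1, 2 and 3, 1, 2 and 0 cell cycle genes were higher. Calls ended for Mcm6 and Top2a with the mean of the probe sets (0.63 and 0.14, adjusted p = 0.0674 and 0.266). Mcm6 was not called without high-fat 3 (adjusted p = 0.0630). Ccnb2 and Top2a were not called whichever high-fat array was left out (adjusted p from 0.0561 to 0.101). Birc5 was not called without high-fat 1 or 3 (adjusted p from 0.0875 to 0.0986).

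**Figure D3:**
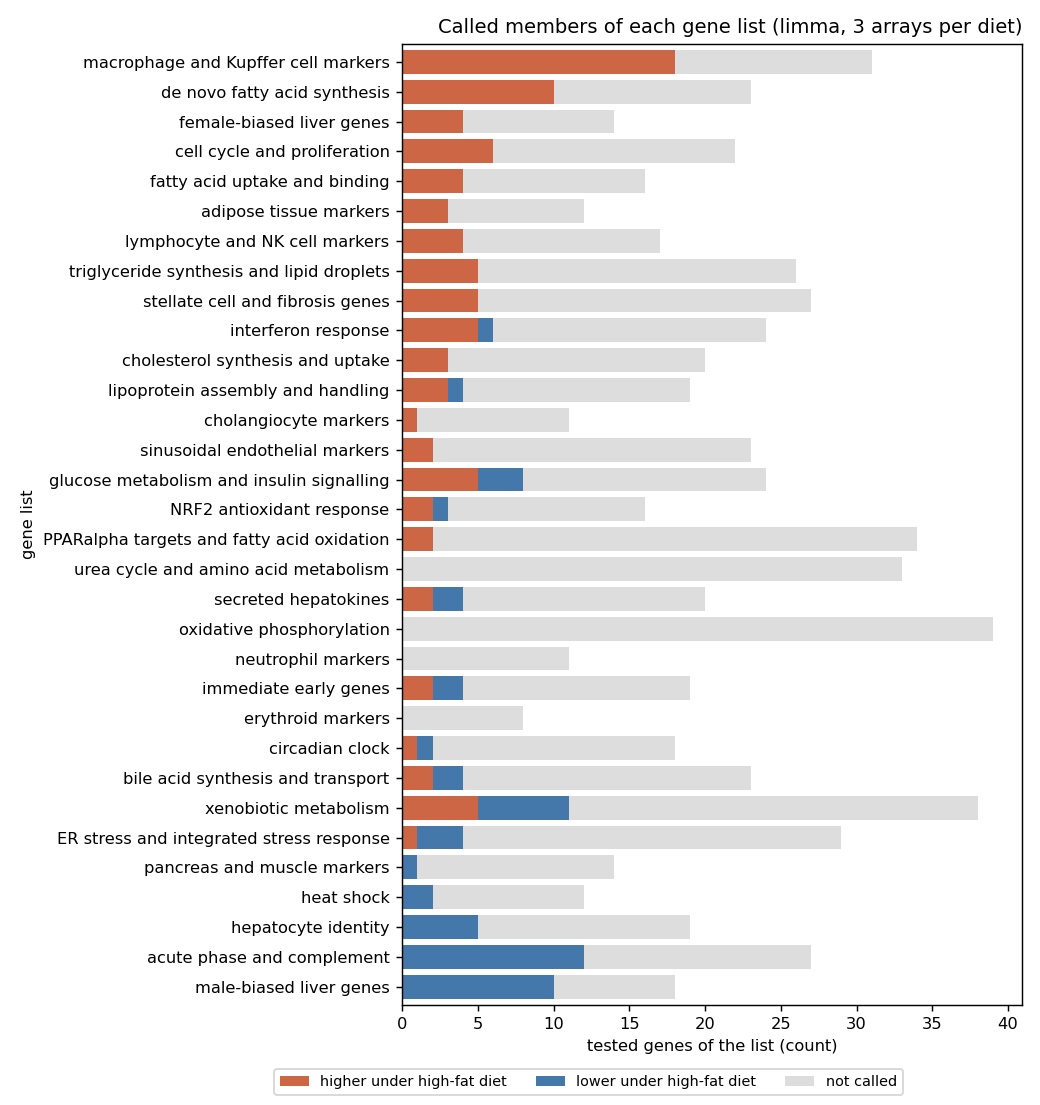
Number of tested genes of each of the 32 lists that were higher (red), lower (blue) or not called (grey) under the high-fat diet at an adjusted p below 0.05. The macrophage list had 18 higher genes of 31, and the male-biased list 10 lower of 18.

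Markers of other cells and tissues were mostly not called. Of 12 adipose tissue markers 3 rose, the lipid genes Cidea, Cidec and Pparg, and 9 were not called (3 higher adjusted over the list alone; camera adjusted p = 0.184). Camera called the adipose list after quantile normalization (adjusted p = 0.0452) and without normal diet 2 (0.0273), and limma called 0 of its members whichever high-fat array was left out and 1 without normal diet 1. Limma called 0 of 11 neutrophil and 0 of 8 erythroid markers, with 1 higher and 1 lower neutrophil genes and 1 higher erythroid gene at an unadjusted p below 0.05 (camera adjusted p = 0.0791 and 0.766). The erythroid median was -0.10 and the mean 0.00451, with camera's direction downward. Prtn3, a neutrophil protease gene, differed by -1.20 ± 0.62 (not called, adjusted p = 0.253), and by -0.37 without normal diet 3. Without normal diet 2 camera called the neutrophil list (0.0321), as it did with a replicate block. Of 11 cholangiocyte markers Pkhd1 rose 1.63-fold and 10 were not called (1 higher and 1 lower adjusted over the list alone). The camera adjusted p was 0.189, and 0.0380 without normal diet 1. Camera also called this list with the level filter at the median. Of 14 pancreas and muscle markers Cela1 was 1.76-fold lower and 13 were not called (1 lower adjusted over the list alone). For these camera gave an adjusted p of 0.0129 (adjusted p = 0.364 with an estimated correlation), which became 0.0580 after cyclic loess. The list was also not called with the mean of the probe sets. Calls ended for Pkhd1 without normal diet 1 (0.69, adjusted p = 0.0531) and for Pkhd1 with a replicate block (0.70, adjusted p = 0.0572). Pkhd1 and Cela1 were not called whichever high-fat array was left out (adjusted p from 0.0852 to 0.128). Prtn3 differed by -0.74 with array weights.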

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

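The counts of probe sets without a single gene symbol were chosen before the result was seen, as were the splits of the arrays. Of 3991 such probe sets tested with limma 65 were higher and 35 lower under the high-fat diet. Among all 27399 probe sets tested one by one, these included, 1460 were called, a larger share. They were singled out because the comparison of named genes does not use them. No explanation was tested.

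The 6 arrays split into 3 and 3 in 10 ways, too few for a share under 0.05. Only the real split, 1 of 10, gave as many genes differing as it did, 1070 against at most 0 in another split, and the same count of splits, 1, 1 and 1, held for genes higher (826 against 0), genes lower (244 against 0) and lists called by camera (19 against 17). In the 9 other splits limma called 0 genes, with 194 to 434 at an unadjusted p below 0.05, and camera called 6 to 17 lists. Both groups of every other split hold arrays of both diets, so a diet difference widens the spread within them. The absence of gene calls there was therefore to be expected. These splits do not show how many genes or lists would be called without a diet difference.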

How the results depend on the processing

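All alternatives were planned before the data were examined except leaving out normal diet 2 and 3 for the counts per list, which was added after their values were seen. Across the arrays left out in turn the count of genes differing ran from 169 to 1245 and lists called from 17 to 21. Higher genes ran from 123 to 933 and lower genes from 46 to 312. The smallest gene counts came without a high-fat array. The fit uses a common variance for both diets, and the median SD of a gene was 0.117 in the high-fat and 0.166 in the normal diet group. Leaving out a high-fat array therefore gives the group with the wider spread more weight in that variance. Whether this accounts for the counts was not tested. At an adjusted p below 0.01 172 genes differed (125 higher, 47 lower), a plain equal-variance test per gene called 18 (12 and 6), and with array weights 373 genes were lower; the cause was not tested. Camera with an estimated correlation called 0 lists, against 2 at an unadjusted p below 0.05 and 14 by fry. Some genes that were not called changed sign, as did 1 called gene: Cyp7a1 was 0.033 after median centring and 0.82, 0.22 and 0.16 without normal diet 1, normal diet 2 and high-fat 2, and Mlxipl 0.024 after median centring and 0.022, 0.093 and 0.17 without normal diet 1, normal diet 2 and high-fat 1. Plin2 was -0.093 without normal diet 1, Cyp4a14 -0.077 without normal diet 3, and the called gene Top2a -0.23 with probe sets without a suffix; the cause was not tested. With each array left out in turn Plin2 ran from -0.093 to 0.44, Cyp4a14 from -0.077 to 2.81, Cyp7a1 from -1.08 to 0.82 and Mlxipl from -0.19 to 0.17. Over named genes and alternatives 2133 values kept direction and side of the threshold, 351 fell below it and 24 passed it. Deviations of same-numbered arrays correlated at -0.0122 to 0.0999 and those of differently numbered arrays at -0.0851 to 0.0789. So few correlations cannot exclude a pairing of the arrays by replicate number. With the replicate block 768 genes differed (581 higher, 187 lower), 674 of them also called without it. Array signal near background compresses folds, and 25 called higher genes had all normal diet arrays at or below the level filter.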

Other observations

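Of the tests given here, those of RNA degradation and of RNA mixed between pools were chosen or revised only after the result was seen, and the others were chosen before. Of 24 interferon response genes 5 rose, 1 fell and 18 were not called (10 and 1 adjusted over the list alone). Ifit2, Ddx58 and Cxcl10 rose 1.63-fold, 1.43-fold and 1.40-fold, and Stat2, which encodes a signal transducer of interferon, was 1.54-fold lower. Camera gave an adjusted p of 0.0404 (adjusted p = 0.441 with an estimated correlation). It became 0.110 after cyclic loess, 0.0846 after quantile normalization, 0.0631 after median centring and 0.199 without normal diet 1. Camera also did not call the list with the level filter at the median, array weights, probe sets without a suffix or a replicate block. Limma called 1 higher member without normal diet 1 and 0 whichever high-fat array was left out, and Ddx58 lost its call after cyclic loess (0.43) and quantile normalization (0.38). Limma called 0 of 39 oxidative phosphorylation genes, with 6 higher at an unadjusted p below 0.05. Camera gave this list an adjusted p of 0.00429 for a shift upward with a mean of 0.15 (adjusted p = 0.431 with an estimated correlation), and 0.953 after cyclic loess. Of 33 urea cycle and amino acid genes limma also called 0, with 2 higher and 4 lower at an unadjusted p below 0.05 (camera adjusted p = 0.986); their median was 0.09 and their mean -0.00550, with a mean of -0.12 after cyclic loess and 0.041 after median centring. Calls ended for Ddx58 and Cxcl10 without normal diet 1 (0.46 and 0.48, adjusted p = 0.0624 and 0.0616), for Ddx58 with the mean of the probe sets (0.18, adjusted p = 0.153) and for Ddx58 and Cxcl10 with a replicate block (0.51 and 0.48, adjusted p = 0.0749 and 0.0716). Ifit2, Ddx58, Cxcl10 and Stat2 were not called whichever high-fat array was left out (adjusted p from 0.0619 to 0.131).

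Of 16 NRF2 antioxidant genes 2 rose, 1 fell and 13 were not called (2 and 1 adjusted over the list alone; camera adjusted p = 0.235, fry adjusted p = 0.0148, upward). Nqo1, a quinone reductase gene, rose 4.42-fold (2.14 ± 0.34) and Nfe2l2, which encodes NRF2 itself, 1.71-fold, while Osgin1 was 1.64-fold lower. Of 18 circadian clock genes Bhlhe40 rose 2.09-fold, Nfil3 was 2.56-fold lower and 16 were not called (1 and 1 adjusted over the list alone; camera adjusted p = 0.201). Dbp, a clock output gene, was 5.02-fold higher (2.33 ± 1.16) without passing (adjusted p = 0.236). It lay at 4.29 in normal diet 3, against 9.33 and 8.59 in normal diet 1 and 2 and 9.54 to 9.90 in the high-fat arrays, and differed by 0.77 without normal diet 3 (adjusted p = 0.0692), 3.29 without normal diet 1 and 2.92 without normal diet 2. Of 19 immediate early genes 2 rose, Sgk1 1.67-fold and Klf6 2.54-fold, 2 fell, Junb 3.31-fold and Gadd45g 3.43-fold, and 15 were not called (4 and 3 adjusted over the list alone; camera adjusted p = 0.743). Of 20 genes of secreted hepatokines 2 rose and 2 fell, among them Fetub (1.89-fold lower), and 16 were not called (3 and 4 adjusted over the list alone; camera adjusted p = 0.658). Whichever high-fat array was left out, limma called 0 higher NRF2 genes and 0 higher immediate early genes, against 1 and 0 without normal diet 1, where 4 immediate early genes were lower. Lower clock genes numbered 1, 0 and 0 and lower hepatokine genes 0, 0 and 1 without high-fat 1, 2 and 3. The immediate early list had a median of 0.0386 and a mean of -0.00244, the latter 0.0440 after median centring. Calls ended for Nfe2l2, Sgk1 and Klf6 without normal diet 1 (0.72, 0.69 and 1.28, adjusted p = 0.0589, 0.0551 and 0.0668), for Osgin1 without normal diet 2 (-0.70, adjusted p = 0.0541) and for Klf6 with a replicate block (1.34, adjusted p = 0.0564). Nqo1, Nfe2l2, Osgin1, Sgk1 and Klf6 were not called whichever high-fat array was left out (adjusted p from 0.0518 to 0.118). Nfil3 was not called without high-fat 2 or 3 (adjusted p from 0.0523 to 0.0613). Fetub was not called without high-fat 1 or 2 (adjusted p from 0.0659 to 0.0685). Klf6 differed by 0.80 with the mean of the probe sets. Dbp differed by 1.54 with array weights.

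The 12 acute phase genes lower under the high-fat diet were weighed against 3 technical explanations. All 12 stayed called without normal diet 3. The mean of the 27 tested members was -1.14 with all arrays (SE 0.209 over genes, not between pools) and -0.97 without normal diet 3. These values argue against that array alone. After cyclic loess the mean was -1.26 and after median centring -1.10. The arrays were already quantile normalized, and the median difference over all tested genes was 0.0033, 0.0011 after cyclic loess and 0.050 after median centring. Further scaling could thus hardly have removed a mean of that size, so it does not decide on scaling. Against normal diet 2 and 3, whose 3' to 5' differences of actin and Gapdh lay within the range of the high-fat arrays, the mean was -1.25, which argues against RNA degradation as far as 2 control transcripts measure it, although a first version of this test, by overlap of the groups, left it undecided. Neither a condition of the normal diet mice that was not recorded nor a shared day of sampling or hybridisation was tested, and both stay open. No biological explanation was tested.

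In normal diet 2 Cidea lay at 8.73, between normal diet 1 and 3 and the high-fat arrays, a level that high-fat RNA making up 14.8% of the pool would give. The 8 other genes at least 8-fold higher in high-fat than in normal diet 1 and 3 implied a median of 17.45%, close to Cidea, but ranged from 1.80 to 167%, and 1 mixture has 1 share. A first reading by that median alone favoured mixing, and the reading by the spread, which leaves it open, replaced it after the values were seen. A test on genes at least 8-fold lower in high-fat than in both normal diet 1 and 3, which had argued against mixing, was dropped, since genes chosen for high values in those arrays tend to lie lower in a further array by selection alone. With genes chosen by normal diet 1 or 3, the level without mixing was taken from the other array. The lower quartiles of the implied share were 32.4% and -5.43% (11 and 16 genes), on either side of Cidea's share. The medians were 54.8% and 33.2% and the upper quartiles 72.6% and 66.7%, all above Cidea's share. In normal diet 2 Cyp2b9 lay at 9.83, above the high-fat mean of 9.10. Hsd3b5, of the dropped test, lay at 4.21 there, against 9.21 and 9.08 in normal diet 1 and 3. A share of 14.8% alone would give neither value. Mixing, a difference between the mice of that pool, or both stay open, and the difference between mice was not tested.

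The 10 lower male-biased and 4 higher female-biased genes were weighed against 2 technical explanations. Xist differed by -0.11 and the 3 tested Y-linked genes by a mean of 0.12. Eif2s3y lay at a mean of 7.87 under normal and 7.98 under high-fat diet. Kdm5d and Uty, at normal diet means of 3.94 and 3.93, were too low to show a fall clearly. Ddx3y, a further planned gene, was not among those tested. The values of Xist and Eif2s3y argue against female mice in the high-fat pools. The abundant hepatocyte transcripts differed by a mean of -0.0225 (SE 0.0550 over genes). The male-biased genes differed by a mean of -1.69 (SE 0.330 over genes) and the female-biased genes by 1.12 (SE 0.338 over genes). These SEs treat the genes of a list as independent and do not measure the spread between pools. The means argue against a lower share of hepatocyte RNA, as far as the abundant transcripts measure it. Of 19 hepatocyte identity genes, however, 5 fell and 0 rose. Socs2 and Igf1, known targets of growth hormone, were 15.2-fold and 1.58-fold lower, but no biological explanation was tested. After cyclic loess the list means were -1.79 and 1.08, and a shared day of sampling stays open.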
